A study of Mus musculus with 3 samples.

How the data were processed

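Tet2 CLIP was carried out on bone marrow derived mast cells of C57BL/6 mice in 3 replicate libraries, which form 1 group. Per the labels' protocols, cells were cross-linked with ultraviolet light, the lysate was treated with RNase I and DNase I, and Tet2 was pulled down with an antibody on magnetic beads. Protein-RNA complexes were separated on a gel and moved to a membrane before RNA was isolated for library preparation. The submitters' processing notes name cutadapt 1.9, STAR 2.4.0i and the mouse build mm10. Per the labels' protocols, peaks were called by a valley-seeking algorithm, which needs a valley of set depth on both sides of a peak. The caller's version, valley depth and any p threshold are not given in the sources used here. The series' design text describes biological triplicates. Each library's column heading bears its replicate number, which was taken as the replicate number of the labels.

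The values used are a signal: the authors deposited, for each library, the chromosome, start, end and normalized height of every peak. The deposited heights of each library sum to 1 and are whole multiples of a fixed step, within 0.05 of a step for 100% of peaks. The step was 1 over 19213, 18270 and 15431 in replicates 1, 2 and 3. Heights were therefore expressed in units of that step. Whether a unit is 1 read is not given in the sources used here, so no result reported below rests on a count model, and sequencing depth is unknown. The lowest heights were 2, 2 and 3 units, and 1271, 1194 and 1083 peaks stood at 3 units, so most low peaks lie at the lowest heights the lists hold. Heights are the authors' values and served to describe, rank and filter peaks within a list. They were also compared between classes of gene within a library and correlated between libraries at shared peaks. Whether starts count from 0 or 1 is not given in the sources used here. They were read as 0-based, because end minus start was never below 1, and coordinates are printed 1-based.

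Gene names and positions came from a RefSeq table of GRCm38.p6, whose coordinates are those of mm10, with 49980 gene spans and 21900 protein-coding genes. The table gives spans without strand, exons or sequence. A peak was assigned to every gene span that held its midpoint, and 561 peaks (6.84%) lay in over 1 span. Without strand, such peaks cannot be credited to a single gene, which holds for peaks of Gata2, Gse1, Cpa3, Pim1, Pfn1 and Xist, among others. For classes, small structural RNA genes came before protein-coding genes, then long non-coding RNA genes, then other loci. The small structural class was set by annotated type and also took in microRNA genes, even within the span of another gene. The planned tests of UTR and coding regions, position within 3′ UTRs, base composition and CpG, motifs and RNA structure need exons or sequence and were not analysed here. In their place stood the share of peaks in gene spans and in the outer parts of protein-coding spans, both set against 10000 random placements per library, and peak height by class of gene, with 100000 permutations. This change from the planned tests was made after the files were seen.

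Sharing between libraries was an overlap of at least 1 nt. Chance sharing came from 1000 draws in which each peak was placed at random in its gene or moved by 300 to 2000 nt. Each pair of libraries shared at most 39.8% of either list, and 165, 101 and 126 of the shared peaks had the same start and end, so no list was a copy of another and the libraries were kept as 3 replicates. The labels name no separate animals or cultures beyond the word biological, so the SD measures the spread between these samples, part of which may be technical. The tests compare genes or peaks and do not measure that spread.

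Gene lists, 21 in number, were fixed before the data were examined, as were the test of the lists and part of the other settings, while the tests of gene spans, span ends and height by class were not. A gene was bound when at least 1 library had a peak in its span. Lists were tested against all other protein-coding genes, or against all other annotated genes for the non-coding and mitochondrial lists, by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. The list of small RNAs was drawn by symbol pattern, and 580 of its 2598 genes have another type in the table. Genes named in the text were fixed by rule: the 10 with the highest single peak, the 5 with the most peaks, up to 4 per list with the highest peak, and Socs3, Adar, Tet2, Kit, Fcer1a, Cpa3 and Malat1. Genes named only in the closing section were chosen after their values were seen. The position of 1 peak mentioned there in a count is not reported here.

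The tests were tried on simulated data first. Among 21900 genes, lists of 30 bound at 3 times the base rate were called in 90% of 20 lists and lists at 4 times in 100%, and 1 of 20 lists at the base rate was called. Of 500 simulated loci shared by 3 libraries, 500 were recovered. Their copies were wider than the shift between them and so always overlapped, which leaves the overlap rule untested for narrow peaks. Alternatives covered the taller peaks only, 1 peak per gene, left-out genes and classes, other rules of overlap and of binding, strata of gene length and each replicate left out in turn. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.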

Results

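Tet2, an enzyme that oxidises 5-methylcytosine, was cross-linked to RNA with ultraviolet light in mouse bone marrow derived mast cells and pulled down with an antibody to the endogenous protein. The cells were grown from bone marrow with interleukin-3 and stem cell factor and carried the mast cell receptors FcεRI and Kit. The question, from the series' design text, was which RNAs Tet2 binds in these cells. The data were 3 biological replicate libraries of 1 group, each with its own list of peaks on the mouse genome build mm10. No input or control-antibody library was analysed here, so heights were compared within the pulled-down RNA alone. Replicate 1 held 3019 peaks, replicate 2 held 2800 and replicate 3 held 2377. The deposited normalized heights of each library summed to 1 and were whole multiples of a fixed step, called a height unit below. The summed heights came to 19213, 18270 and 15431 units in replicates 1, 2 and 3. The median peak stood at 4 units in every library, and the tallest at 223, 217 and 223 units. Median peak width was 53 nt in each library.

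The tallest Tet2 peak in all 3 libraries lay in Rn7s1, a gene for 7SL, the RNA of the signal recognition particle, at chromosome 12, position 69159435. It reached 223, 217 and 223 units and took 1.26% ± 0.157 (SD, n = 3) of the summed height of a library. The other 7SL gene, Rn7s2, carried 204, 197 and 212 units at position 69361340 of the same chromosome, or 1.17% ± 0.176 (SD, n = 3). Rpph1, the RNA subunit of ribonuclease P, carried 114, 112 and 102 units on chromosome 14 (0.622% ± 0.0348, SD, n = 3). Rmrp, the RNA of ribonuclease MRP, carried 65, 70 and 58 units on chromosome 4 (0.366% ± 0.0241, SD, n = 3). The 18S ribosomal RNA locus Rn18s-rs5, annotated as a pseudogene, lies on chromosome 17 (39846354 to 39848202). It held 3 peaks in each library, and together they took 2.21% ± 0.276 (SD, n = 3) of the height.

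Protein-coding and long non-coding genes also held narrow peaks of this size. Jarid2, a cofactor of Polycomb repressive complex 2, carried 131, 126 and 133 units on chromosome 13, and Zc3h7a, a zinc finger protein, carried 139, 133 and 127 units on chromosome 16. A peak of 130, 127 and 140 units fell where the spans of Cmss1 and Filip1l overlap on chromosome 16. The long non-coding gene Gm36876 on chromosome 11 carried 175, 174 and 182 units. A peak of 167, 155 and 163 units lay inside the immunoglobulin kappa locus Igk at chromosome 6, position 69516479. When peaks within 100 nt of each other were merged into sites, all 25 of the tallest sites were present in all 3 libraries. They made up 0.927% of the peaks and 16.3% ± 1.76 (SD, n = 3) of the summed height, with a median peak width of 2 nt. Of these sites, 8 lay in no gene span, among them sites 273 and 2659 nt from Rn18s-rs5. The other peaks of Jarid2 stood at 3 or 4 units. Sequence and read placement were not analysed here, so reads that match several places in the genome cannot be told apart at these sites. Spans came without exons or strand, so exon, intron and UTR positions were not analysed here.

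Genes with the most peaks were different from those with the tallest ones. Gse1, a chromatin corepressor-associated protein on chromosome 8, held 12, 15 and 9 peaks. Gata2, a transcription factor of mast cells and their progenitors (chromosome 6, 88193891 to 88207032), held 14, 12 and 9. Csf2rb2, the interleukin-3 receptor beta chain specific to the mouse (chromosome 15, 78282507 to 78305721), held 11, 12 and 11. Col5a1, a collagen V chain on chromosome 2, held 12, 10 and 11 peaks and took 1.65% ± 0.130 (SD, n = 3) of the height. Its tallest peak lay at 27980503 in replicate 1 (59 units), and at 28007794 and 28007796 in replicates 2 and 3 (70 and 58 units). Kmt2d, a histone H3 lysine methyltransferase on chromosome 15, held 8, 13 and 8 peaks. At Col5a1, 8 loci were shared by all 3 libraries, against 5 at Gata2, 4 at Csf2rb2 and 3 each at Gse1 and Kmt2d.

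The libraries shared tall peaks, and most low peaks were found in 1 library. Peaks that overlapped by at least 1 nt formed 5969 loci, of which 661 (11.1%) held a peak in all 3 libraries, 904 (15.1%) in 2 and 4404 (73.8%) in 1. Replicates 1 and 2 shared 996 peaks, or 33.0% and 35.6% of their lists. For replicates 1 and 3 the number was 881 (29.2% and 37.1%), and for replicates 2 and 3 it was 948 (33.9% and 39.8%). Random placement of each peak within its own gene shared 28.1 to 33.3 peaks on average, far below the 786 to 897 seen inside genes. No placement of 1000 reached the observed number (one-sided permutation p = 0.001 for each pair, the smallest these draws can give). Placement was even over each span, without regard to exons, so the test cannot separate shared binding sites from shared coverage of the same RNA. Heights of shared peaks correlated at Pearson r of 0.814, 0.816 and 0.821 on the log2 scale and at Spearman rho of 0.638, 0.627 and 0.635. These are correlations across peaks, which are not independent replicates.

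At the gene level, 2093, 1975 and 1717 genes held a peak in replicates 1, 2 and 3, and 778 genes held 1 in every library, 693 of them protein-coding. Low peaks were shared least. Each peak was set against both other libraries, which gives 6 pairings. Of peaks of 3 or 4 units, 22.9% (exact 95% interval 22.1 to 23.7) overlapped a peak of another given library, against 48.2% (46.7 to 49.7) at 5 to 9 units and 72.1% (69.9 to 74.2) at 10 units or more. Above that height the overlap did not go on rising: it averaged 75.6% at 10 to 19 units and 65.5% at 20 or more, and was lower at 20 or more in all 6 pairings. The tallest peaks were also the narrowest, with a median width of 3 nt at 50 units or more and 63 nt at 3 units. When a midpoint within 200 nt also counted as found, a rule chosen after the overlap was seen, the shares became 27.6%, 57.0% and 95.2%. Intervals cover counting error only, and they may be too narrow because each peak enters more than 1 pairing.

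**Figure D1:**
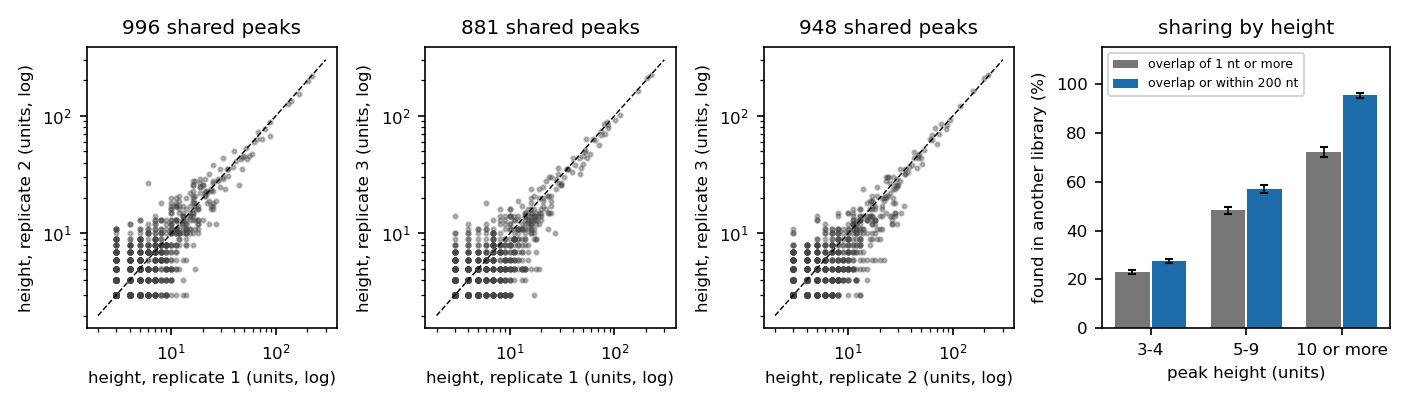
Heights of shared peaks in each pair of replicates on log axes in height units, with the diagonal dashed, and the share of peaks found in another library in percent by height class, with exact 95% intervals as error bars. The pairs share 996, 881 and 948 peaks, and sharing is lowest at 3 or 4 units under both rules.

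Peaks fell in annotated genes and toward the ends of those genes. Gene spans held 91.1% ± 0.459 (SD, n = 3) of the peaks, against 48.8% of positions placed at random on the same chromosomes. In protein-coding spans of at least 10000 nt, 38.3% ± 0.987 (SD, n = 3) of the peaks lay in the outer 10% of the span, 5% at each end, where even placement gave 10.0%. Both shares passed a two-sided permutation test in each library (p = 0.0002, the smallest that 10000 placements can give). The placements took no account of which parts are transcribed or exonic, and no control library was analysed here. The test therefore cannot separate Tet2 binding from the positions of transcribed RNA. Protein-coding genes held 86.8% ± 0.235 of the peaks and 72.1% ± 2.00 of the summed height (SD, n = 3). Small structural RNA genes held 0.758% ± 0.154 of the peaks and 4.31% ± 0.403 of the height (SD, n = 3), and long non-coding RNA genes 2.82% ± 0.0768 and 4.81% ± 0.215. The small structural class also took in microRNA genes. Positions outside gene spans held 8.85% ± 0.459 of the peaks and 15.2% ± 1.16 of the height (SD, n = 3).

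Peaks in small structural RNA genes, such as Rn7s1, Rn7s2, Rpph1 and Rmrp, had median heights of 6, 4.5 and 8 units in replicates 1, 2 and 3. The median was 4 units in protein-coding genes, in long non-coding RNA genes and outside genes. Against protein-coding genes, the difference in median log2 height was 0.58 in replicate 1, 0.16 in replicate 2 and 1.00 in replicate 3. A two-sided permutation test, adjusted over 6 class pairs, gave adjusted p of 0.0346 in replicate 1 and 4.2e-04 in replicate 3, and 1 in replicate 2. By medians, most of which sit at 4 units, the small RNA class did not pass in every library, and it rested on 19, 26 and 17 peaks. By means, a setting added after seeing the data, the log2 difference averaged 1.29 and passed in all 3 libraries (permutation, largest adjusted p = 3.0e-05). Of the 25 tallest sites, 5 lay in this class. Means were not taken without them, so a few tall sites may carry the difference. No other pair passed by medians in any library. By means, protein-coding genes were lower than long non-coding RNA genes (-0.38, permutation, largest adjusted p = 9.6e-04) and than positions outside genes (-0.46, largest adjusted p = 3.0e-05).

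Genes of the mast cell identity list carried Tet2 peaks well above the rate of other genes. Whether each member is particular to mast cells was not analysed here. Of 27 mast cell identity genes, 16 held a peak in at least 1 library (59.3%), against 3070 of 21873 other protein-coding genes (ratio 4.22, Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 1.93e-07 over 21 lists). The mean per library was 48.1% ± 3.70 (SD, n = 3), against 7.87% ± 0.779 for all protein-coding genes. Over 12 alternative settings, the ratio of the list ran from 3.70 to 14.3. After Gata2, the tallest peaks of the group were in Slc18a2, the vesicular monoamine transporter that loads histamine into granules (11, 13 and 9 units), Csf2rb, the common beta chain of the interleukin-3 receptor (13, 11 and 10 units), and Kit, the stem cell factor receptor (12, 5 and 7 units). Kit held 8 peaks in replicate 1 and 1 each in replicates 2 and 3. Cpa3, the mast cell carboxypeptidase, which shares peaks with overlapping spans, held 1 peak of 4, 5 and 4 units. Fcer1a, the alpha chain of FcεRI, held no peak in any library. Markers of macrophages (1 of 16 bound), neutrophils (0 of 16), lymphocytes (0 of 14) and erythroid or megakaryocytic cells (2 of 16) did not pass the test, with exact adjusted p of 0.835, 0.212, 0.299 and 1, and the lists with no bound gene were too short for a deficit to pass. Set directly against these 4 lists, which together had 3 of 62 genes bound, the mast cell list was higher (Fisher's exact test, adjusted p = 8.99e-08 over 4 comparisons of lists chosen after the shares were seen). Without RNA levels or a control library, this comparison cannot separate Tet2 binding from the expression of these genes in mast cells.

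Signalling genes downstream of Kit, FcεRI and cytokine receptors also carried peaks above the rate of other genes. In the FcεRI and Kit signalling list, 17 of 30 genes held a peak (ratio 4.04, Fisher's exact adjusted p = 1.93e-07), led by the kinases Prkcd (11, 0 and 3 units), Prkcb (9, 3 and 3 units) and Pik3cd (6, 8 and 3 units) and the adaptor Gab2 (0, 6 and 0 units). This group differed most between libraries, with 12, 5 and 8 genes bound in replicates 1, 2 and 3 and 2 bound in all 3. Requiring a peak in all 3 libraries ended its call (ratio 2.11, exact adjusted p = 0.368), and no gene of the list held a locus shared by all 3 (ratio 0). The JAK-STAT and SOCS list had 17 of 34 genes bound (ratio 3.56, exact adjusted p = 1.81e-06). Its tallest peaks were in Csf2rb2 (29, 27 and 20 units), Socs1, an inhibitor of JAK kinases (11, 18 and 6 units), the kinase Pim1 (13, 7 and 10 units) and Socs4 (9, 11 and 9 units). Socs3, another cytokine signalling inhibitor, held 1 peak in replicate 1, 2 in replicate 2 and none in replicate 3, with a tallest height of 4, 4 and 0 units. Csf2rb and Csf2rb2 are near-identical neighbours, and how reads were shared between them was not analysed here.

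Among cytokine, chemokine and immediate-early genes, 17 of 42 were bound (ratio 2.88, exact adjusted p = 5.71e-05). Zfp36l2, an RNA-binding protein that shortens mRNA half-life, had the tallest peak (13, 4 and 5 units), followed by the transcription factor Jund (3, 8 and 3 units), the cytokine Lif (4, 7 and 3 units) and Ier3 (6, 7 and 3 units). Haematopoietic transcription factors had 13 of 31 genes bound (ratio 2.98, exact adjusted p = 3.02e-04). Irf8 reached 10, 8 and 15 units, Runx1 reached 7, 13 and 8 units with 7, 7 and 4 peaks, Runx3 reached 6, 7 and 3 units and Etv6 reached 7, 4 and 4 units. With only loci shared by all 3 libraries, a setting added after seeing the data, the transcription factor list missed the threshold (ratio 4.61, exact adjusted p = 0.0618).

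**Figure D2:**
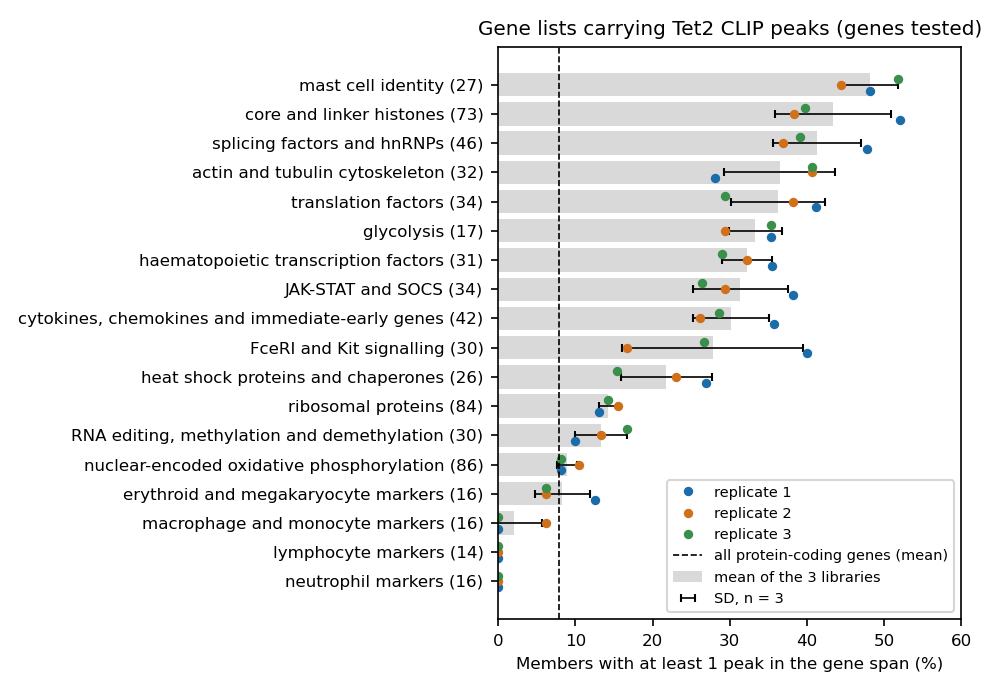
Share of the genes of each protein-coding list with at least 1 peak in the gene span, in percent, as the mean of the 3 libraries (bars), each replicate (points) and the SD (error bars, n = 3), with the number of genes tested in parentheses. The dashed line is the mean of all protein-coding genes, 7.87%. Mast cell identity genes average 48.1% and histones 43.4%, while no lymphocyte or neutrophil marker holds a peak.

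Genes for histones, translation factors, splicing factors and the cytoskeleton carried peaks above the rate of other genes. Of 73 core and linker histone genes, 45 held a peak (61.6%, ratio 4.42, exact adjusted p = 8.2e-20), with 38, 28 and 29 bound in replicates 1, 2 and 3. H2B genes on chromosome 13 had the tallest peaks: H2bc9 reached 44, 26 and 26 units, H2bc4 reached 6, 27 and 18, H2bc3 reached 27, 12 and 10 and H2bc8 reached 24, 16 and 17. Translation factors had 21 of 34 genes bound (ratio 4.41, exact adjusted p = 9.58e-10), among them the helicase Eif4a1 (26, 34 and 17 units), the poly(A)-binding protein Pabpc1 (16, 20 and 16 units), the scaffold Eif4g1 (18, 13 and 13 units) and the elongation factor Eef2 (10, 11 and 14 units). Splicing factors and hnRNPs had 27 of 46 bound (ratio 4.19, exact adjusted p = 1.78e-11), with Ddx17 at 10, 5 and 7 units, Son at 3, 4 and 8, Hnrnpd at 7, 8 and 4 and Hnrnpl at 3, 4 and 6. Actin and tubulin cytoskeleton genes had 18 of 32 bound (ratio 4.01, exact adjusted p = 1.25e-07), led by Actb, which encodes beta-actin (23, 32 and 15 units), and Coro1a (12, 11 and 11 units). In the same list, Myl12b held 1 peak of 10 units in replicate 2 alone, and Pfn1 reached 4, 5 and 7 units. With only loci shared by all 3 libraries, the cytoskeleton list missed the threshold (ratio 4.47, exact adjusted p = 0.0618). Histone genes include near-identical copies, and how reads were shared among them was not analysed here.

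Glycolysis, heat shock and ribosomal protein genes passed the test, and oxidative phosphorylation genes did not. Glycolysis genes had 8 of 17 bound (ratio 3.35, exact adjusted p = 0.00217), with Hk1 at 7, 7 and 5 units, Pkm at 5, 3 and 4, Slc2a1 at 4, 3 and 3 and Aldoa at 4, 0 and 3. Heat shock proteins and chaperones had 9 of 26 bound (ratio 2.46, exact adjusted p = 0.0105), led by Hspa5, the chaperone BiP, at 16, 5 and 3 units, Canx at 4, 8 and 9, Hspa4 at 8, 3 and 3 and Cct4 at 7, 5 and 3. The heat shock call was lost without replicate 1 (ratio 2.11, exact adjusted p = 0.0862) and with at least 2 peaks per gene (ratio 1.97, exact adjusted p = 0.404). Ribosomal protein genes had 23 of 84 bound (27.4%, ratio 1.95, exact adjusted p = 0.00236), and their tallest peaks were in Rpl13a (11, 3 and 5 units), Rpl27a (5, 8 and 4 units), Rpl15 (3, 3 and 6 units) and Rpl32 (0, 0 and 6 units). The ribosomal protein list missed the threshold with at least 2 peaks per gene, at a ratio of 2.15 (exact adjusted p = 0.0736), and with a peak in all 3 replicates (ratio 1.51, exact adjusted p = 0.462). When only loci shared by all 3 libraries counted, glycolysis (ratio 2.79, exact adjusted p = 0.426), heat shock (3.66, 0.190) and ribosomal protein genes (1.70, 0.422) all missed it. The share of ribosomal protein genes bound was below the 61.6% of histone genes (Fisher's exact test, adjusted p = 3.04e-05) and the 61.8% of translation factors (adjusted p = 7.1e-04, exact), without regard to gene length. Nuclear-encoded oxidative phosphorylation genes had 12 of 86 bound, the rate of the background (ratio 0.990, exact adjusted p = 1), although Cox7c reached 23, 12 and 11 units and Atp5j 8, 13 and 12. In that group Ndufa8 reached 5, 9 and 5 units and Atp5a1 6, 9 and 0. No peak lay on the mitochondrial genome, where 2 listed genes were tested.

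Genes that edit, methylate or demethylate nucleic acids were not set apart. Of 30, 7 were bound (23.3%, ratio 1.66, exact adjusted p = 0.238). Tet3, a paralog of Tet2, held 1, 2 and 1 peaks of at most 4, 5 and 5 units. Alkbh5, an RNA demethylase, held 1 peak of 5 units in replicate 3, the export factor Alyref reached 3, 4 and 4 units and Wtap, of the m6A methyltransferase complex, 0, 3 and 3. Tet2 itself and the adenosine deaminase Adar held no peak in any library. The single macrophage marker bound was Adgre1, with 3 units in replicate 2, and the megakaryocytic genes were Itga2b (4 units in each library) and Gp1ba (3 units in replicate 1).

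Of 20 listed nuclear and other long non-coding RNAs, 6 were bound, against 6.93% of all other annotated genes (ratio 4.33, Fisher's exact test, adjusted p = 0.00297). Neat1, the paraspeckle scaffold on chromosome 19, reached 25, 28 and 15 units with 3, 7 and 4 peaks, and the imprinted H19 on chromosome 7 reached 25, 28 and 18 units. Malat1 held 1 peak of 10, 18 and 15 units in replicates 1, 2 and 3. Xist on chromosome X, which shares peaks with an overlapping span, reached 11, 9 and 6 units. The list of small nuclear and small nucleolar RNAs, which also holds Rn7s1, Rn7s2, Rpph1 and Rmrp, had 21 of 2598 genes bound (0.808%, ratio 0.111, exact adjusted p = 1.13e-53). With 10 strata of span length, set after seeing the data, the ratio turned to 1.37 (permutation, adjusted p = 0.146). The strata also kept protein-coding and other genes apart, so this list was no longer compared with all annotated genes. Gene length and gene type thus changed together, and their shares in the deficit cannot be told apart. Under the same strata the ratio rose to 14.8 for histones and 3.28 for ribosomal proteins, each past the threshold. It fell to 2.96 for FcεRI and Kit signalling, 3.14 for JAK-STAT and SOCS and 2.6 for haematopoietic transcription factors, which still passed, and stood at 4.63 for translation factors. For the long non-coding RNAs the ratio was 15.5 and passed. As protein-coding genes had left that background, it cannot be set beside the 4.33 above as an effect of length. Every ratio of lists was against annotated genes, expressed or not, because RNA levels in these cells were not analysed here.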

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

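Of 32 results, 19 kept their direction and their side of the threshold, or for counts stayed within 1.5 times, under every alternative run, and so did 339 of 361 values. Settings fixed before the data were examined come first. With the taller peaks only, loci shared by all libraries fell to 426 and genes to 457, since fewer peaks entered. With at least 2 peaks per bound gene, heat shock proteins (ratio 1.97) and ribosomal proteins (2.15) no longer passed. Leaving out each replicate gave 881 to 996 shared loci, because sharing was then asked of 2 libraries. It gave ratios of 2.11 to 2.87 for heat shock proteins, lost without replicate 1, and a small RNA minus protein-coding height difference of 0.37 to 0.79 (log2), which passed without replicate 2.

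Among settings chosen after seeing the data, strata of span length turned the small RNA list to a ratio of 1.37. Those strata also kept protein-coding and other genes apart. With a peak required in all 3 replicates, the FcεRI and Kit signalling (2.11) and ribosomal protein (1.51) lists were lost. With only loci shared by all 3 libraries, 7 lists passed instead of 13. FcεRI and Kit signalling then had no bound gene (ratio 0), and haematopoietic transcription factors (4.61), heat shock (3.66), actin and tubulin (4.47), glycolysis (2.79) and ribosomal proteins (1.70) missed the threshold. Peaks in protein-coding genes were then lower than those outside genes by a log2 difference of -0.82, which passed. Overlap of 50% of both peaks left 392 shared loci. Differences of mean log2 height passed for small RNA minus protein-coding genes (1.29), protein-coding minus long non-coding genes (-0.38) and protein-coding minus no gene (-0.46). Apart from the smaller peak sets, the cause of these shifts was not tested.

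Of the settings fixed beforehand, those on UTR order, longest transcript, exons, windows, motif length and exonic length were not run, because exons and sequence were not used here. Height rank within a gene was not run, because all peaks of a gene share a class. With 1 peak per gene, bound genes are the same by construction. No paired analysis was possible because there is only 1 group. Depth is unknown, and peaks near 3 units set the limit of what a library lists.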

Other observations

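All tests in this part were chosen after the results they measure were seen.

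Genes on the X chromosome carried few Tet2 peaks. Of 966 protein-coding genes on chromosome X, 52 were bound in any library (5.38%), against 3034 of 20665 on the autosomes (14.7%), an odds ratio of 0.331 (Fisher's exact test, two-sided, p = 3.27e-19). At the rate of autosomal protein-coding genes of like span length, 137 X genes would have been bound. In all 3 replicates, 12 X genes were bound (1.24%), against 681 autosomal genes (3.30%), with p = 1.11e-04 by Fisher's exact test. Xist, a long non-coding RNA of chromosome X whose span shares peaks with that of Tsix, held 2, 2 and 1 peaks. Chromosome Y held 3, 2 and 2 peaks, none in a protein-coding gene. RNA levels of X genes were not analysed here.

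Several of the tallest sites lay outside gene spans. A site at chromosome 17, 39846054 to 39846081, held 169, 176 and 154 units and lay 273 nt from Rn18s-rs5, and another at 39843669 to 39843695 held 108, 84 and 90 units, 2659 nt from it. Whether both belong to a longer ribosomal RNA transcript around Rn18s-rs5 was not analysed here. Lying outside a gene span thus does not place them outside a transcribed unit. A site at chromosome 16, 17222347 to 17222359, with 102, 93 and 92 units, lay 8365 nt from the nearest gene span, that of Rimbp3. On chromosome 3, the site at 5860754 to 5860793 held 85, 86 and 78 units and lay 109459 nt from any span. Within genes, Cdk8 held 86, 89 and 89 units, Snrnp70 held 87, 88 and 84 and Basp1 held 72, 72 and 56.

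Most loci, 73.8%, were found in 1 library alone. The first test of sampling at this depth asked whether 90% of peaks of 10 units or more overlap a peak of another library, and the share was 72.1% (exact 95% interval 69.9 to 74.2), short of that bound. As each peak enters more than 1 pairing, this interval and those below may be too narrow. The first test of differing peak borders found another library's midpoint within 200 nt for 11.8% of all unshared peaks, which argues against borders as the main cause. Split by height after these outcomes, 82.8% (79.1 to 86.1) of unshared peaks of 10 units or more had such a midpoint, against 6.19% (5.67 to 6.73) at 3 or 4 units, and 95.2% (94.1 to 96.2) of tall peaks were then found in another library. Borders may thus account for tall unshared peaks, and sampling stays open for low ones, with the caveat that the rule which passed was chosen after the overlap rule had failed; no biological explanation was tested, since there is 1 group.

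Rn7s1 and Rn7s2 carried peaks of nearly equal height. Rn7s1 was the higher in all 3 libraries, by 19, 20 and 11 units, and held 51.97% of their summed height on average, with libraries from 51.3% to 52.4%. A random split of reads between identical copies would put each library on either side of 50% with equal chance. All 3 libraries can then fall on the same side at random, so they are too few to test such a split. Reads shared between near-identical copies may or may not account for these heights. The peak lay 141 nt from the start and 159 nt from the end of the 299 nt Rn7s1 span, and 158 nt and 142 nt in Rn7s2. Sequence and read placement were not analysed here, so equal binding of both RNAs stays open too. Binding was not separated from RNA abundance, because no control library was analysed here.

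Of 8196 peaks, 5 stood at 2 units, below the 3 units at which the rest begin, with 1 in replicate 1 and 4 in replicate 2. All 5 stood out of the sorted order of their list, against 24 of 8191 others (0.293%, Fisher's exact test, two-sided, p = 3.86e-13). Nearly all of the 24 were in replicate 1, so this pooled share hides a difference between the lists. The 2-unit peak of Socs3, at chromosome 11, 117967284 to 117967424, was 141 nt wide and had no overlap in another library. Among the 24 was the peak listed second in replicate 1, in Pdcd6ip, of 37 units, likewise 141 nt wide and with no overlap in another library, and so was the 167-unit Igk peak of replicate 1, 1 nt wide and shared by all 3 libraries. Being out of order was thus not limited to low or unshared peaks. The test restates what was seen in the lists, and the cause was not tested. Without peaks under 3 units, the JAK-STAT and SOCS list kept its call, and no result changed its side of a threshold.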
